A study of Mus musculus with 12 samples.

How the data were processed

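RNA was measured in whole liver of C57BL6/J mice, in 12 libraries that fall into 3 groups of 4. The groups were chow diet with saline vehicle, a MASH-inducing diet with vehicle, and the MASH diet with FGF21 at 1 mg per kg per day, with 4 weeks of treatment. MASH is metabolic dysfunction-associated steatohepatitis, a fatty liver disease with inflammation and scarring. FGF21 is a hormone of the fibroblast growth factor family that acts through FGF receptors together with the co-receptor Klb. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and enriched with oligo-dT. The submitters' processing notes name Trim Galore 6.10, Salmon 1.10.2 and the mouse build mm10. The gene annotation, the step from transcripts to genes and the filter on genes are not given in the sources used here.

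The authors deposited a table of 14822 gene symbols with a value per library. Its names call the values FPKM and normalized counts, and the test plan was written for FPKM. The columns of the table sum to just under 1000000 each, so the deposited values were read as TPM (values scaled to a total of 1000000 per library), rounded by the authors to 1 decimal. The planned test on a log scale was used with TPM in place of FPKM and was otherwise the same. TPM keeps no depth, so the number of reads behind each value is unknown and no counting intervals or detection floors can be given. The precision rests on the spread between the 4 libraries of a group. Nothing in the labels states that the 4 libraries of a group came from separate animals. If they did not, the p-values measure only the spread between these samples, which may be technical. All 12 columns were matched to samples by the library names in the labels, and 0 columns were left unmatched.

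Genes with a TPM of at least 1 in at least 4 libraries entered the tests, which left 10988 genes. Values were taken as log2(TPM + 1), and every fold change below is on this scale, which understates the change of genes with low values. A linear model with 3 groups was fitted to all 12 libraries in limma 3.58.1 (R 4.3.3), with the trend and robust options of its moderated test. The 3 contrasts were MASH vehicle against chow, FGF21 against MASH vehicle, and FGF21 against chow. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Single values per library, such as a share of the total, were compared between groups with exact permutation tests, for which 0.0286 is the smallest two-sided p that 4 libraries against 4 can give. Coordinates, GC content and length came from the GENCODE M21 annotation of build GRCm38, the assembly also called mm10. A GC content was found for 10810 of the genes tested (98.4%).

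Before the data were examined, 40 gene lists were fixed, 15 of them markers of cell types, together with the tests, the alternatives and the rule for naming genes. Lists with at least 3 tested members were tested with camera, a competitive test in limma that compares a list with all other genes, at a preset correlation of 0.01 between genes. The p-values of camera were adjusted over all lists and the 3 contrasts. Some genes stand in more than 1 list, such as 2 of 14 cholangiocyte and progenitor, 1 of 12 neutrophil and 3 of 20 recruited macrophage markers. The lists of adipocyte genes and of pancreas, muscle and mesothelial genes had fewer tested members, 2 each, and were not tested. Genes to be named were, for each of the first 2 contrasts, the 4 largest rises and the 4 largest falls among called genes whose groups did not overlap, with a mean TPM of at least 1 in at least 1 of the groups, leaving out predicted genes, the Mup family and immunoglobulin segments. To these came the 2 members with the smallest p in each of the 10 lists with the smallest camera p, or the most abundant member where none passed, and Fgf21, Klb, Col1a1, Acta2, Timp1, Adgre1, Cyp7a1 and Scd1. For FGF21 against chow the rule took 3 rises, 3 falls and 4 lists. The acinar pancreas genes, Adipoq, Plin4 and the tested neutrophil markers were named outside this rule. For other genes the text says where this was so. Some results are left out because they need items withheld for evaluation.

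The overlap of calls between the diet contrast and the FGF21 contrast was set against 100 simulations of unchanged groups, against independent lists, and against the 6 splits of the MASH vehicle libraries into 2 and 2. Alternatives were other pseudocounts (0.1 and 5), no filter and a stricter filter, median-of-ratios scaling, quantile normalization, fits of only the groups compared, array weights, a test without trend and robust options, a block for the replicate number, each library left out in turn, and other list tests. Added after seeing the data were the removal of the trend with GC content, of the trends with GC content and length, of FGF21 replicates 1 and 3, and of Mup and mitochondrially encoded genes from the total. Each trend was subtracted as a whole fit per library, which also recentred the libraries. Removal of a trend thus also takes out a shift shared by all genes. The scripts were tested on simulated data with 100 genes changed by a log2 change of 1 and 100 by 2 in each contrast. In the contrast of MASH vehicle against chow 94% and 98% of these were recovered, with 7.89% false calls. In the contrast of FGF21 against MASH vehicle 91% and 98% were recovered, with 2.83% false calls. In the contrast of FGF21 against chow 92% and 99% were recovered, with 4.13% false calls. Figures were drawn with matplotlib.

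Salmon shares reads between similar transcripts, so values of near-identical paralogs are uncertain. Among the genes named this holds for the Gsta, Gstm, Saa, Orm, Cyp2a, Cyp4a and Mup families.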

Results

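The series measured polyadenylated RNA of whole mouse liver in 3 groups of 4 libraries, written here as chow, MASH vehicle and FGF21 (the MASH diet with FGF21). The title of the series states a reversal of MASH by FGF21 with actions on brain and liver, and the table holds liver only. The total per library was 999842 to 999891 TPM in chow and MASH vehicle. FGF21 replicates 1 and 3 fell short of 1000000 TPM by 7968 and 8206 and FGF21 replicate 4 by 1217, against at most 158 in the other libraries. Because TPM keeps no depth, the sequencing depth of the samples is unknown. Pearson's r of log2(TPM + 1) across genes was 0.983 to 0.994 between chow libraries, 0.989 to 0.992 between MASH vehicle libraries and 0.958 to 0.988 between FGF21 libraries, against 0.921 to 0.984 between libraries of different groups. Genes are not independent replicates, so these values only describe the libraries. The first principal component held 50.6% of the variance and the second 20.1%.

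The makeup of the total differed between the diets. The 13 mitochondrially encoded genes took 11.2% ± 1.43 of the total in chow (SD, n = 4), 6.60% ± 0.503 in MASH vehicle and 5.67% ± 1.33 in FGF21. Mup genes, which encode the major urinary proteins that liver secretes, took 6.53% ± 0.638, 3.6% ± 0.662 and 3.54% ± 1.30. Both shares were lower in every MASH vehicle library than in every chow library (exact permutation test, two-sided p = 0.0286, adjusted p = 0.0429 over 12 comparisons), and neither passed between FGF21 and MASH vehicle (p = 0.257 and 0.971). The median log2 fold change of all genes was 0.19 for MASH vehicle against chow, −0.03 for FGF21 against MASH vehicle and 0.20 for FGF21 against chow. With Mup and mitochondrially encoded genes left out of the total the first and the last were still 0.08 and 0.09, and 64.8% of diet calls were higher (2257 higher, 1226 lower). Median-of-ratios scaling moved them to −0.01 and 0.02. Changes of single genes are to be read relative to that shift.

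The first comparison, MASH vehicle against chow, asks what the MASH diet did to liver RNA. Lists of macrophages, matrix, lipid droplets and fatty acid oxidation passed as higher on the MASH diet at the preset correlation of camera, and lists of cholesterol synthesis, of periportal hepatocytes and of the mitochondrial genome as lower. None of these lists passed with an estimated correlation (adjusted p = 0.167 to 0.32), and the mitochondrial list was also lost with the GC trend removed. The largest rises were in Cfd, the complement factor adipsin, from 2.90 ± 1.88 to 248 ± 203 TPM (mean ± SD, n = 4 in each group here and below). Next came the lipid droplet proteins Cidea, from 2.15 ± 1.68 to 92.3 ± 34.1, and Cidec, from 15.2 ± 10.4 to 385 ± 60.2, and the injury gene Ly6d, from 2.95 ± 1.52 to 97.8 ± 28.9. The largest falls were in Nnmt, nicotinamide N-methyltransferase, from 138 ± 17.3 to 11.2 ± 7.64 TPM, and in the sterol synthesis gene Idi1, from 102 ± 21.6 to 7.60 ± 0.906. Next came Enho, which encodes the peptide adropin, from 12.1 ± 6.97 to 0.80 ± 0.258, and the sterol synthesis gene Msmo1, from 87.5 ± 13.9 to 14.3 ± 3.15. Each of these 8 genes had its MASH vehicle libraries on 1 side of all chow libraries, which the naming rule required.

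Their log2 fold changes and limma adjusted p-values were 5.71 ± 0.848 (SE) and 0.00026 for Cfd (chromosome 10, 79890853 to 79892655) and 4.97 ± 0.655 and 0.000105 for Cidea (chromosome 18, 67343604 to 67367785). For Cidec and Ly6d they were 4.80 ± 0.485 and 1.53e-05 (chromosome 6, 113424634 to 113435760) and 4.67 ± 0.349 and 2.98e-06 (chromosome 15, 74762056 to 74763620). Among the falls they were −3.75 ± 0.440 and 4.67e-05 for Nnmt (chromosome 9, 48591877 to 48605153) and −3.56 ± 0.560 and 0.000391 for Idi1 (chromosome 13, 8885501 to 8892451). Enho and Msmo1 had −2.70 ± 0.332 and 6.21e-05 (chromosome 4, 41638144 to 41640324) and −2.55 ± 0.429 and 0.000648 (chromosome 8, 64718139 to 64733792). These positions are whole genes, protein-coding in the annotation of build GRCm38.

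Of 25 cholesterol biosynthesis genes, 20 fell and 0 rose on the MASH diet, 21 adjusted over the list alone, with a median log2 fold change of −1.35 (camera adjusted p = 1.09e-16, adjusted p = 0.218 with an estimated correlation). Tm7sf2, a sterol reductase, fell from 281 ± 12.1 to 101 ± 11.2 TPM, and Mvk, mevalonate kinase, from 35.1 ± 4.27 to 12.8 ± 1.61. Of 30 genes of fatty acid oxidation and ketogenesis, 26 rose, 27 adjusted over the list alone (median 0.71, camera adjusted p = 6.47e-07, adjusted p = 0.282 with an estimated correlation). Its peroxisomal members Ehhadh and Pex11a rose from 89.0 ± 9.54 to 332 ± 66.3 TPM and from 48.9 ± 8.08 to 135 ± 14.5. Of 17 lipid droplet proteins 11 rose, 13 adjusted over the list alone, with Hsd17b11 at 59.8 ± 5.28 and 155 ± 12.1 TPM (camera adjusted p = 0.000124, adjusted p = 0.282 with an estimated correlation). Scd1, the main fatty acid desaturase of liver, rose from 4822 ± 1294 to 13485 ± 2036 TPM.

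Markers of recruited and lipid-associated macrophages rose in 14 of 16 cases, 15 adjusted over the list alone, with a median log2 fold change of 2.05 (camera adjusted p = 1.72e-09, adjusted p = 0.167 with an estimated correlation). Lpl, lipoprotein lipase, rose from 1.27 ± 0.171 to 20.5 ± 2.37 TPM, Lgals3, galectin-3, from 3.75 ± 0.545 to 31.6 ± 9.36, and Adgre1, which encodes the macrophage antigen F4/80, from 1.43 ± 0.287 to 6.53 ± 1.52. Lysosome and phagocytosis genes rose in 21 of 27 cases and 1 fell, Lamp2, named after its value was seen (21 and 1 adjusted over the list alone, camera adjusted p = 3.41e-06, adjusted p = 0.218 with an estimated correlation). The complement genes C1qb and C1qc rose from 38.5 ± 7.08 to 140 ± 16.1 TPM and from 35.5 ± 5.75 to 117 ± 13.9. All 7 tested genes of dendritic cells and antigen presentation rose, 7 adjusted over the list alone (camera adjusted p = 0.000719, adjusted p = 0.282 with an estimated correlation). Cd74 was at 116 ± 23.6 and 348 ± 52.4 TPM and H2-Aa at 29.2 ± 9.39 and 92.2 ± 14.7. Markers of resident Kupffer cells, the macrophages native to liver, rose in 9 of 12 cases, 12 adjusted over the list alone (camera adjusted p = 0.000719, adjusted p = 0.282 with an estimated correlation). Because the RNA is of whole liver, members of the marker lists here and below, Lpl among them, can come from other cells too.

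Fibrillar collagen and matrix genes rose in 22 of 24 cases, 23 adjusted over the list alone, with a median log2 fold change of 0.99 (camera adjusted p = 1.16e-06, adjusted p = 0.32 with an estimated correlation). Timp1, an inhibitor of matrix proteases, was at 0.15 ± 0.129 TPM in chow and 2.40 ± 0.860 in MASH vehicle, Sparc at 25 ± 7.36 and 89.0 ± 21.3, and Col1a1, a chain of collagen I, at 1.65 ± 0.465 and 11.3 ± 7.64. Stellate cell and myofibroblast markers rose in 11 of 15 cases, 11 adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.345 with an estimated correlation). Only 5 were called with median-of-ratios scaling, 6 with quantile normalization and 7 with the GC trend removed. The myofibroblast gene Acta2, smooth muscle actin, was at 2.55 ± 0.379 and 4.33 ± 1.18 TPM and did not pass (limma adjusted p = 0.391). That p rests on the spread of Acta2 in FGF21 replicates 1 and 3, and without these libraries it was 0.0119. Sinusoidal endothelial markers rose in 9 of 16 cases, 10 adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.533 with an estimated correlation).

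Genes of hepatocyte injury, senescence and tumours rose in 9 of 13 cases and 1 fell, Tff3, named after its value was seen (10 and 1 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.305 with an estimated correlation). Chemokines and inflammatory cytokines rose in 10 of 13 cases and 1 fell, Il18, likewise named after its value was seen (10 and 1 adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.234 with an estimated correlation). Cell cycle genes rose in 12 of 14 cases (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.305 with an estimated correlation), and all 3 tested neutrophil markers, Lcn2, Csf3r and S100a9, rose, 3 adjusted over the list alone (camera adjusted p = 0.00308, adjusted p = 0.218 with an estimated correlation). Of 25 NRF2 and glutathione genes, 15 rose and 1 fell, Gstm6, named after its value was seen (16 and 2 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.395 with an estimated correlation).

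Periportal hepatocyte markers fell in 9 of 16 cases and 1 rose, Cdh1, named after its value was seen (9 and 1 adjusted over the list alone, camera adjusted p = 6.77e-06, adjusted p = 0.263 with an estimated correlation). The urea cycle genes Ass1 and Asl fell from 7086 ± 349 to 2739 ± 558 TPM and from 1032 ± 115 to 402 ± 55.1. Mitochondrially encoded genes fell in 8 of 13 cases, 9 adjusted over the list alone (camera adjusted p = 1.14e-06, adjusted p = 0.257 with an estimated correlation), with mt-Cytb at 12031 ± 3189 and 4237 ± 1213 TPM and mt-Nd4l at 6116 ± 754 and 3120 ± 612. The call of mt-Nd4l was lost with GC and length trends removed (−0.61, limma adjusted p = 0.0901). With the GC trend removed this list no longer passed (camera adjusted p = 0.0966), its median moved from −0.55 to −0.11, and 6 members fell. Of 23 genes of bile acid synthesis and transport, 9 fell and 4 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.000137, adjusted p = 0.218 with an estimated correlation). Akr1d1, a steroid reductase of bile acid synthesis, fell from 56.8 ± 16.1 to 16.1 ± 3.18 TPM, the efflux pump Abcc4 rose from 0.35 ± 0.0577 to 1.40 ± 0.294, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (12.9 ± 3.63 and 9 ± 7.03 TPM, limma adjusted p = 0.361). The other 3 that rose were Abcc3, Acox2 and Abcb4, named after their values were seen.

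Drug-metabolising enzymes fell in 10 of 26 cases and rose in 5 (Fmo5, Ugt1a1, Nr1i2, Aldh1a7 and Fmo1, named after their values were seen; 10 and 6 adjusted over the list alone, camera adjusted p = 0.00229, adjusted p = 0.263 with an estimated correlation). Of 19 male-biased hepatocyte genes 6 fell and 3 rose, Cyp4a12b, Cyp4a12a and Ces2e, named after their values were seen (7 and 3 adjusted over the list alone, camera adjusted p = 0.00259, adjusted p = 0.489 with an estimated correlation). Chow replicate 2 stood at −0.82 from the chow mean on this list, against 0.14 to 0.43 in the other chow libraries and −0.40 to −0.33 in MASH vehicle. With quantile normalization male-biased genes (0.0935), drug-metabolising enzymes (0.0635) and cAMP targets (0.117) did not pass, nor did cAMP targets with median-of-ratios scaling (0.108). Hepatocyte secreted proteins, with 4 of 20 lower (Fgb, Fgg, Ttr and Apoh) and 2 higher (Hpx and Hp), passed as lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0397, adjusted p = 0.395 with an estimated correlation). With quantile normalization their direction turned (adjusted p = 0.781). The targets of cAMP and glucocorticoids, with Pde4b, Klf9 and Adra1b lower and Pde4d higher of 16, passed narrowly (3 and 1 adjusted over the list alone, camera adjusted p = 0.0491, adjusted p = 0.305 with an estimated correlation). The members of these 2 lists were named after their values were seen. The hepatocyte secreted proteins did not pass without chow replicate 4 (0.153), MASH vehicle replicate 2 (0.0832) or FGF21 replicate 1 (0.0529). The cAMP targets did not pass without chow replicate 3 (0.106), MASH vehicle replicates 3 (0.103) or 4 (0.0567), or FGF21 replicates 1 (0.0625), 2 (0.0522) or 3 (0.0509). Neither passed without FGF21 replicates 1 and 3 together (0.0538 and 0.0619). Endogenous Fgf21 rose from 4.22 ± 2.01 to 21.6 ± 11.4 TPM (log2 fold change 2.07 ± 0.337, limma adjusted p = 0.000515). Its co-receptor Klb was at 9.65 ± 1.37 and 7.92 ± 1.51 TPM and did not pass (adjusted p = 0.202), but passed as lower with median-of-ratios scaling (adjusted p = 0.0364), with quantile normalization (0.0223) and with the GC trend removed (0.0159).

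In all, limma called 3242 genes higher and 861 lower in MASH vehicle than in chow at an adjusted p under 0.05, and 3633 and 1046 genes had groups that did not overlap (42.6% of genes, where chance gives 2.86%). Of 38 lists tested, 22 passed with camera, 14 higher and 8 lower, and 0 passed with an estimated correlation, where 5371 single genes had an unadjusted p under 0.05 and the rotation test fry called 28 lists. The share of calls that were higher was 79.0% on TPM, against 44.6% with median-of-ratios scaling (1592 higher, 1980 lower) and 45.9% with quantile normalization (1683 higher, 1986 lower). With median-of-ratios scaling 14 of 16 macrophage markers, 20 of 24 matrix genes, 18 of 27 lysosome genes and 18 of 30 fatty acid oxidation genes were still called higher, and 22 of 25 cholesterol biosynthesis genes lower. Kupffer cell markers called higher went from 9 to 6 of 12 and NRF2 and glutathione genes from 15 to 9 of 25. Fold changes rose with the GC content of the gene (Spearman's rho 0.41 across 10810 genes), and with that trend removed limma called 1507 genes higher and 1383 lower, which kept 2080 of the 4103 calls. That removal also took the median log2 fold change of all genes from 0.19 to −0.003. Median-of-ratios scaling, which moved the median to −0.01 without any removal of a GC trend, kept 2453 of the calls. Leaving out single libraries gave 2317 to 3739 genes higher and 487 to 1195 lower. The count of lower genes was 545 without chow replicate 1, 487 without chow replicate 2, 509 without MASH vehicle replicate 2 and 491 without MASH vehicle replicate 4.

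**Figure D1:**
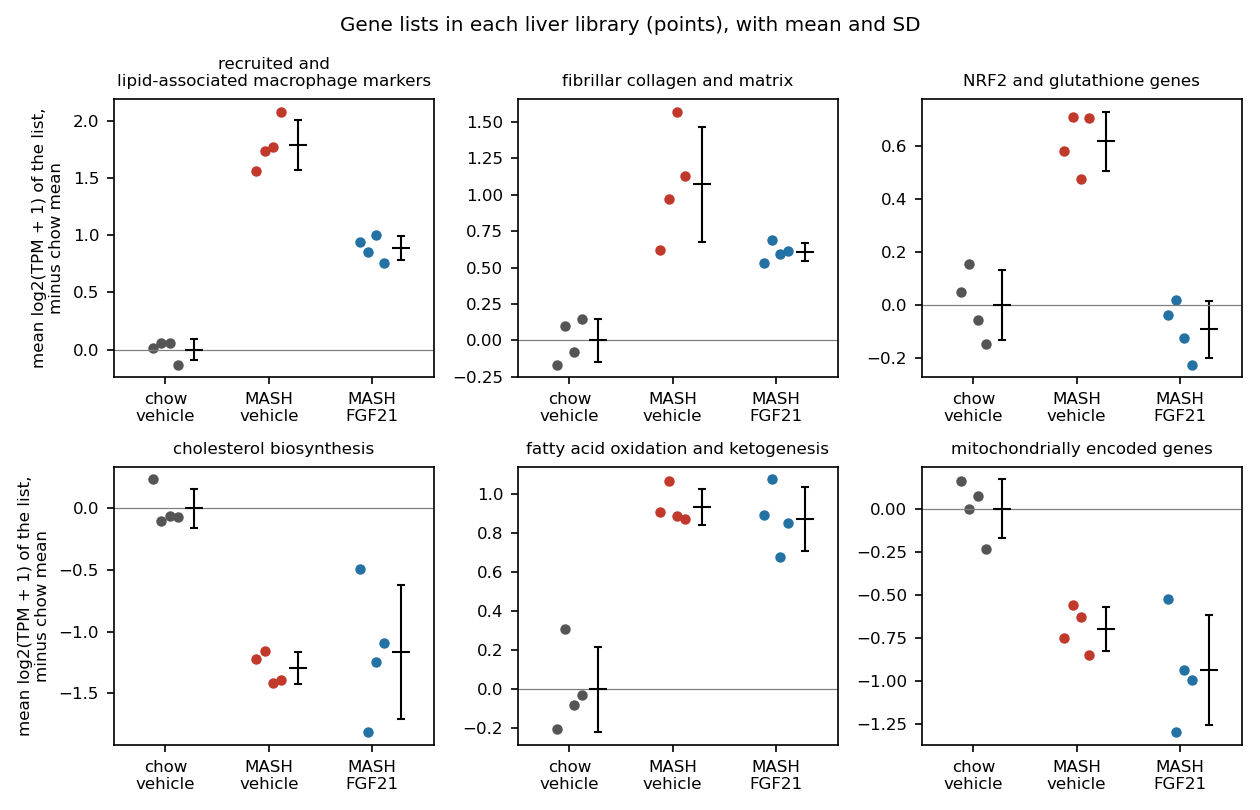
Each panel shows a gene list, with the mean log2(TPM + 1) of its tested members per library minus the chow mean on the y axis and the 3 groups on the x axis; points are libraries (n = 4 per group) and bars give the mean and SD. The MASH vehicle libraries lie above all chow libraries for the macrophage, matrix, glutathione and fatty acid oxidation lists and below them for the other 2 lists.

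The second comparison, FGF21 against MASH vehicle, asks what 4 weeks of FGF21 did on the MASH diet. Lists of lipid-associated macrophages, glutathione enzymes, injury, acute phase proteins, collagen and lipid droplets passed as lower with FGF21 at the preset correlation of camera, with 5 to 12 members of each past the threshold. None of these lists passed with an estimated correlation (adjusted p = 0.167 to 0.44). The cholesterol biosynthesis list, low on the MASH diet, did not pass in either direction. The largest falls were in Cfd, from 248 ± 203 to 20.2 ± 19.9 TPM, and in Cidea, from 92.3 ± 34.1 to 10.1 ± 9.25. Close behind were the glutathione transferases Gsta1, from 20.9 ± 5.82 to 1.48 ± 0.793, and Gstm3, from 333 ± 122 to 41.4 ± 13.9, whose values are uncertain because close paralogs share reads. The largest rises were in Enho, from 0.80 ± 0.258 to 4.80 ± 1.45 TPM, and in Lepr, the leptin receptor gene, from 1.30 ± 0.283 to 5.92 ± 2.34. Sorbs3 rose from 22.3 ± 3.47 to 66.0 ± 30.5 and the retinol dehydrogenase gene Rdh16f2, from 43.9 ± 8.60 to 126 ± 51.0. In each of these 8 genes all FGF21 libraries lay on 1 side of all MASH vehicle libraries, which the naming rule required.

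The log2 fold changes and limma adjusted p-values were −3.97 ± 0.848 (SE) and 0.0123 for Cfd and −3.52 ± 0.655 and 0.00655 for Cidea. Gsta1 and Gstm3 had −3.16 ± 0.301 and 0.000115 (chromosome 9, 78230656 to 78242684) and −2.96 ± 0.274 and 0.000115 (chromosome 3, 107963696 to 107969283). Among the rises they were 1.66 ± 0.332 and 0.0091 for Enho and 1.53 ± 0.205 and 0.00122 for Lepr (chromosome 4, 101717404 to 101815352). Sorbs3 and Rdh16f2 had 1.43 ± 0.278 and 0.00807 (chromosome 14, 70180468 to 70211989) and 1.43 ± 0.227 and 0.00289 (chromosome 10, 127866474 to 127877317). The fall of Cfd was −4.58 without FGF21 replicate 2 and −3.16 without replicate 4, and that of Cidea was −2.91 without replicate 1. With a pseudocount of 5 Enho no longer passed (adjusted p = 0.0508).

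**Figure D2:**
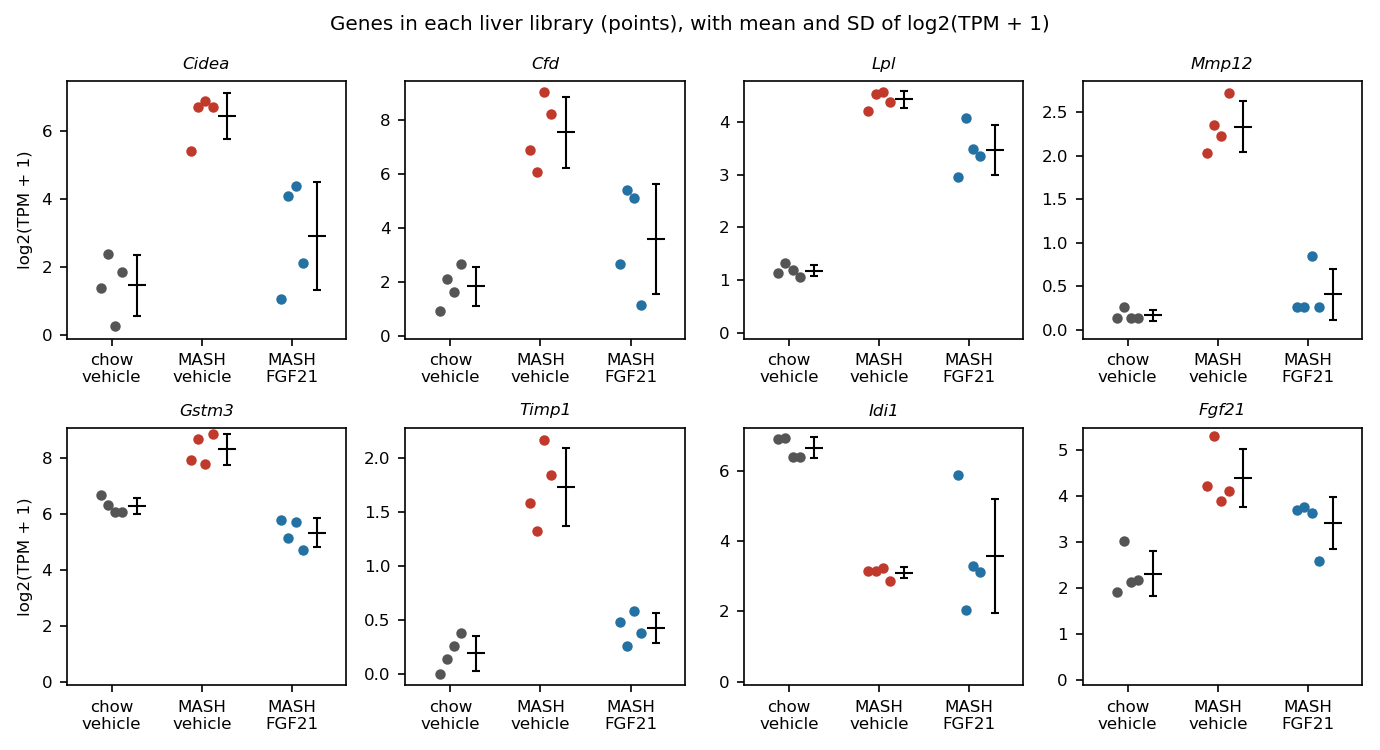
Each panel shows a gene, with log2(TPM + 1) per library on the y axis and the 3 groups on the x axis; points are libraries (n = 4 per group) and bars give the mean and SD. Cidea, Cfd, Mmp12, Gstm3 and Timp1 are lower in every FGF21 library than in every MASH vehicle library, and Idi1 is high in FGF21 replicate 1 alone of the 4 FGF21 libraries.

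Markers of recruited and lipid-associated macrophages fell with FGF21 in 10 of 16 cases, 14 adjusted over the list alone, with a median log2 fold change of −0.79 (camera adjusted p = 2.01e-10, adjusted p = 0.167 with an estimated correlation). Mmp12, a macrophage elastase, fell from 4.12 ± 1.07 to 0.35 ± 0.300 TPM and Clec7a, the receptor dectin-1, from 6 ± 0.970 to 1.90 ± 0.356, while Adgre1 was at 6.53 ± 1.52 and 4.45 ± 0.777 and did not pass (limma adjusted p = 0.0887; it passed without MASH vehicle replicate 3, at 0.0411, and with array weights, at 0.0216). Chemokines and inflammatory cytokines fell in 4 of 13 cases, 6 adjusted over the list alone (camera adjusted p = 0.0001, adjusted p = 0.214 with an estimated correlation). Ccl2 fell from 6.42 ± 1.73 to 1.68 ± 0.680 TPM and Cxcl1 from 5.38 ± 1.74 to 2.45 ± 0.387, a call lost with GC and length trends removed (−0.65, limma adjusted p = 0.0617). The other 2 were Cxcl10 and Il1b, named after their values were seen. The list of dendritic cells and antigen presentation passed as lower (camera adjusted p = 0.00337, adjusted p = 0.305 with an estimated correlation) with 0 of 7 members past the threshold over all genes and 5 lower adjusted over the list alone. Its most abundant member, Cd74, was at 348 ± 52.4 and 230 ± 63.1 TPM (limma adjusted p = 0.0562). It passed without FGF21 replicate 1 (0.00879), without replicates 1 and 3 (0.012), with array weights (0.0208), with the stricter filter (0.0492) and with the GC trend removed (0.0437).

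NRF2 and glutathione genes fell in 12 of 25 cases and rose in 0, with 15 lower adjusted over the list alone (median −0.35, camera adjusted p = 1.12e-09, adjusted p = 0.214 with an estimated correlation). Genes of hepatocyte injury, senescence and tumours fell in 5 of 13 cases, 6 adjusted over the list alone (camera adjusted p = 1.26e-05, adjusted p = 0.257 with an estimated correlation). The annexin gene Anxa5 was at 171 ± 36.4 and 52.5 ± 7.91 TPM and Ly6d at 97.8 ± 28.9 and 13.4 ± 5.69. The other 3 were Sprr1a, Anxa2 and Tnfrsf12a, named after their values were seen. Acute phase genes fell in 8 of 22 cases (10 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.000728, adjusted p = 0.282 with an estimated correlation). The serum amyloid gene Saa1 fell from 438 ± 99.6 to 80.3 ± 28.5 TPM and the orosomucoid gene Orm2 from 48.4 ± 14.8 to 10.1 ± 1.49. Both have close paralogs, so their values are uncertain. Cell cycle genes fell in 4 of 14 cases, 6 adjusted over the list alone (camera adjusted p = 4.72e-05, adjusted p = 0.257 with an estimated correlation). Cdc20 fell from 6.35 ± 3.45 to 1.25 ± 0.265 TPM and Birc5 from 2.90 ± 1.21 to 0.90 ± 0.0816. The other 2 were Ccnd1 and Cdk1, named after their values were seen.

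Fibrillar collagen and matrix genes fell in 8 of 24 cases and 1 rose, Fn1, the fibronectin gene, named after its value was seen (10 and 1 adjusted over the list alone, camera adjusted p = 0.000132, adjusted p = 0.44 with an estimated correlation). Timp1 fell from 2.40 ± 0.860 to 0.35 ± 0.129 TPM and Loxl2, a collagen cross-linking oxidase, from 3.12 ± 0.585 to 1.35 ± 0.265. Col1a1 fell from 11.3 ± 7.64 to 3.40 ± 1.17 TPM (log2 fold change −1.32 ± 0.343, limma adjusted p = 0.0287). That call was lost without MASH vehicle replicate 3 (−0.95, 0.0594), MASH vehicle replicate 4 (−1.26, 0.0746) or FGF21 replicate 4 (−1.20, 0.0752). It was also lost without FGF21 replicates 1 and 3 together (0.0574), with array weights (0.0851) and with only the 2 groups fitted (0.0676). Stellate cell and myofibroblast markers did not pass (camera adjusted p = 0.9), with Des alone of 15, named after its value was seen, higher over all genes and 0 adjusted over the list alone. With the GC trend removed 0 were higher, and without FGF21 replicates 1 and 3 there were 0 higher and 2 lower. Acta2 was at 15.2 and 18.5 TPM in FGF21 replicates 1 and 3, 2 and 2.2 in replicates 2 and 4, and 2.90 to 5.70 in MASH vehicle. It did not pass (0.51 ± 0.509, limma adjusted p = 0.572), and without FGF21 replicates 1 and 3 it passed as lower (−0.75, 0.0142).

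Lipid droplet proteins fell in 6 of 17 cases, 7 adjusted over the list alone, with Hilpda at 6.95 ± 1.15 and 3.88 ± 0.780 TPM (camera adjusted p = 0.000421, adjusted p = 0.282 with an estimated correlation). Genes of fatty acid and triglyceride synthesis fell in 6 of 24 cases and rose in 2, Mlxipl and Dgat2, named after their values were seen (8 and 2 adjusted over the list alone, camera adjusted p = 0.0327, adjusted p = 0.418 with an estimated correlation). This list did not pass without MASH vehicle replicate 2 (0.0757), FGF21 replicate 1 (0.246) or FGF21 replicate 2 (0.0562). Scd1 fell from 13485 ± 2036 to 4545 ± 2161 TPM (log2 fold change −1.69 ± 0.306, limma adjusted p = 0.00568). Fatty acid oxidation and ketogenesis did not pass (camera adjusted p = 0.54). Of 25 cholesterol biosynthesis genes 1 rose, the regulator Srebf2, named after its value was seen, and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.134). FGF21 replicate 1 stood at −0.50 from the chow mean on this list, against −1.82 to −1.09 in the other FGF21 libraries. Without FGF21 replicates 1 and 3 the median went from 0.10 to −0.18, with 4 members lower and 2 higher, and the list did not pass (0.51). Without FGF21 replicate 2 it passed as higher (camera adjusted p = 0.000198). Oxidative phosphorylation passed as lower with a median of −0.17 (camera adjusted p = 0.00203, adjusted p = 0.218 with an estimated correlation), but 0 of 29 members passed, over all genes or adjusted over the list alone, and its most abundant member, Cox4i1, was at 955 ± 66.0 and 833 ± 117 TPM (limma adjusted p = 0.272; 0.0481 without FGF21 replicates 1 and 3).

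Lysosome and phagocytosis genes fell in 3 of 27 cases, Cd63, Tyrobp and Ctss, and 1 rose, Tfeb (3 and 1 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.305 with an estimated correlation). Neutrophil markers fell in 2 of 3 cases, Lcn2 and S100a9 (2 adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.282 with an estimated correlation). Markers of cholangiocytes and progenitors fell in 3 of 8 cases, the osteopontin gene Spp1 and the keratins Krt8 and Krt18 (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.305 with an estimated correlation). The RNA is of whole liver, and the called members of these marker lists can come from other cells too. No change in the share of a cell type follows from them. Hepatocyte secreted proteins passed as higher with Itih4 and Amt of 20 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.305 with an estimated correlation), and sinusoidal endothelial markers with Eng of 16 (1 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.511 with an estimated correlation). Amt encodes a mitochondrial enzyme that is not secreted, so its rise is no evidence on secreted proteins. Female-biased hepatocyte genes passed as higher with 0 of 11 members past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.511 with an estimated correlation). On the insulin and growth hormone axis 5 of 17 genes rose, Igfals, Irs2, Stat5b, Igfbp2 and Akt2, and Igfbp3 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0416, adjusted p = 0.257 with an estimated correlation). Of 16 targets of cAMP and glucocorticoids Crtc2 and Pde4b rose and Pde4d fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0416, adjusted p = 0.293 with an estimated correlation). The genes of this paragraph were named after their values were seen.

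Several of these calls were lost without a single library. Sinusoidal endothelial markers did not pass without MASH vehicle replicate 4 (0.0634) or FGF21 replicate 4 (0.0935), cholangiocyte markers without MASH vehicle replicate 3 (0.0504), and female-biased genes without FGF21 replicate 1 (0.183). The insulin and growth hormone axis did not pass without MASH vehicle replicates 2 (0.0832) or 4 (0.0595) or FGF21 replicates 1 (0.0968) or 2 (0.0697), nor with quantile normalization (0.0665). The cAMP targets did not pass without MASH vehicle replicates 3 (0.0762) or 4 (0.0612) or FGF21 replicate 1 (0.16), nor with the GC trend removed (0.0517). Endogenous Fgf21 was at 21.6 ± 11.4 TPM in MASH vehicle and 10.3 ± 3.55 with FGF21 and did not pass (−0.96 ± 0.337, limma adjusted p = 0.088). Klb was at 7.92 ± 1.51 and 10.7 ± 2.18 TPM (adjusted p = 0.144), and passed as higher without FGF21 replicates 1 and 3 (0.0299). Cyp7a1 was at 9 ± 7.03 and 12.2 ± 10.2 TPM (adjusted p = 0.839).

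FGF21 replicates 1 and 3 also held transcripts of acinar pancreas. Cela2a, a pancreatic elastase gene, was at 425 and 616 TPM in them and at 0.10 to 0.50 in the other 10 libraries, and Cela1, which liver libraries also held at 28.2 to 74.6 TPM, was at 428 and 578. Without these 2 libraries limma called 1767 genes higher and 1221 lower with FGF21, and 17 lists passed. Of the lists above, lysosome genes (camera adjusted p = 0.098), female-biased genes (0.301), neutrophil markers (0.0619), fatty acid and triglyceride synthesis (0.212), the insulin and growth hormone axis (0.114) and cAMP targets (0.206) were then not past the threshold. Gained were mitochondrially encoded genes as lower (0.00805), periportal markers as higher (0.0173), gluconeogenesis and glycolysis as higher (0.0355) and the endoplasmic reticulum stress response as lower (0.0477).

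**Figure D3:**
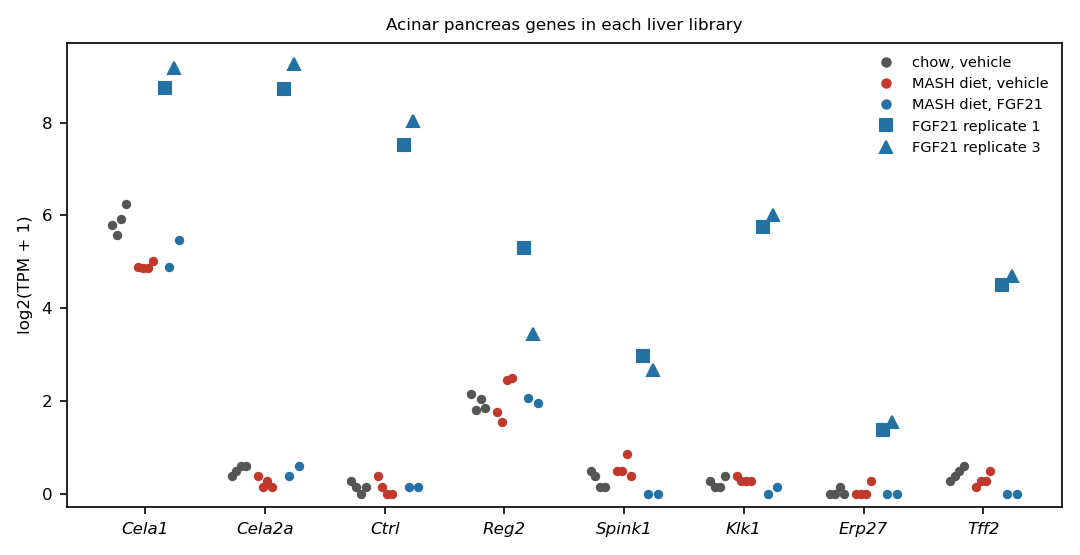
The y axis gives log2(TPM + 1) per library for the 8 acinar pancreas genes present in the table, which stand on the x axis, and colours mark the 3 groups (n = 4 each). FGF21 replicates 1 (squares) and 3 (triangles) are the 2 highest libraries for each of the 8 genes, with Cela2a at 425 and 616 TPM.

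With all 12 libraries, limma called 662 genes higher and 470 lower with FGF21 than with vehicle, and 821 and 728 genes had groups that did not overlap (14.1% of genes, where chance gives 2.86%). Of 38 lists tested, 19 passed with camera, 5 higher and 14 lower, and 0 passed with an estimated correlation, where 2842 single genes had an unadjusted p under 0.05 and fry called 16 lists. Fold changes rose with GC content (Spearman's rho 0.39 across 10810 genes), and with that trend removed limma called 450 genes higher and 606 lower, which kept 765 of the 1132 calls and turned the share of higher calls from 58.5% to 42.6%. The count moved with single libraries: the sum of both directions was 567 without MASH vehicle replicate 1, 613 without replicate 3 and 549 without replicate 4, and 2217 without FGF21 replicate 1, 592 without replicate 2 and 743 without replicate 4. Genes lower were also 296 without MASH vehicle replicate 2. With only these 2 groups fitted limma called 348 genes higher and 283 lower, and with array weights 1415 and 1054.

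**Figure D4:**
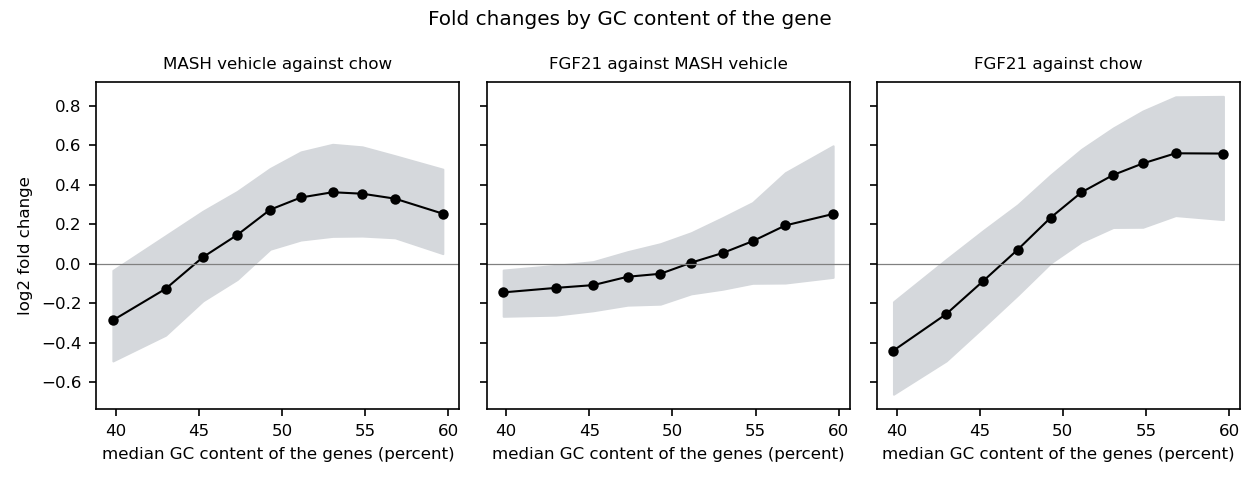
Genes with a GC content were put in 10 bins of equal size, and each point gives the median log2 fold change of a bin against its median GC content, in percent, with the middle 50% of genes shaded. The median moves from −0.29 in the lowest bin to 0.25 in the highest for MASH vehicle against chow, from −0.15 to 0.25 for FGF21 against MASH vehicle, and from −0.44 to 0.56 for FGF21 against chow.

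Whether FGF21 turned back the changes of the diet was asked by the overlap of calls. Of the 4103 genes called for the diet, 417 (10.2%) were called in the opposite direction with FGF21, 348 of them higher on the diet and lower with FGF21, and 78 (1.90%) were called in the same direction. The other 3608 were not past the threshold with FGF21. In FGF21 against chow, 3102 of the diet calls (75.6%) were called in the direction of the diet. That contrast shares the chow libraries with the diet contrast, which favours equal signs. Of the 417 opposite calls, 130 were still called against chow in the direction of the diet and 265 were not past the threshold. An opposite call is thus not always a return to chow. At the level of lists, 12 passed in opposite directions in the diet contrast and in FGF21 against MASH vehicle. Only 1, the sinusoidal endothelial markers, passed as higher in both, where independent calls would give 6.21 and 4.79. With an estimated correlation 0 lists passed in either contrast, so 0 were opposite. With the MASH vehicle libraries split between the contrasts a mean of 11 lists were opposite.

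The contrasts share the MASH vehicle libraries, which favours opposite signs. Simulated unchanged groups gave a mean of 0.01 opposite calls, but almost no gene was called in them, so that value is no reference for the overlap. Independent lists of the same sizes would give 191 opposite and 232 in the same direction. With the MASH vehicle libraries split 2 and 2 between the contrasts, a mean of 124 genes (105 to 150) were opposite and 12.8 (1 to 25) in the same direction. Across genes the fold changes of the contrasts had a Pearson's r of −0.26, a covariance of −0.05 and, in simulated unchanged groups, −0.50 and −0.02. The observed covariance minus the simulated was −0.03, and with split libraries the covariance was −0.04. The opposite count was 269, 255 and 209 without MASH vehicle replicates 1, 2 and 4. The count in the same direction was 410 without FGF21 replicate 1, beside 557 opposite. Without FGF21 replicates 1 and 3 it was 890 and exceeded the 606 opposite, so the balance of opposite over same calls turned there. The same-direction count was 38, 40 and 33 without chow replicates 1, 2 and 3, 17, 28, 21 and 15 without MASH vehicle replicates 1 to 4, and 25 without FGF21 replicate 2.

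The third comparison, FGF21 against chow, asks what still differed from chow in treated livers. Lists of cholesterol biosynthesis and mitochondrially encoded genes passed as lower than in chow at the preset correlation of camera, and lists of fatty acid oxidation, sinusoidal endothelium and Kupffer cells as higher. None of these lists passed with an estimated correlation (adjusted p = 0.234 to 0.374), and with the GC trend removed the mitochondrial genes called lower went from 10 to 6. The largest differences upward were in Cyp2a4, from 0.87 ± 1.48 TPM in chow to 24.9 ± 24.6 with FGF21 (log2 fold change 3.66 ± 0.577, limma adjusted p = 0.000424, chromosome 7, 26307169 to 26315088). Cyp2a4 was at 61.5 TPM in FGF21 replicate 1 and 9.4 to 16.8 in the other FGF21 libraries. Without FGF21 replicates 1 and 3 its fold change was 2.90, below the 4.38 of Adam11. Values of Cyp2a4 and Cyp4a14 are uncertain because of close paralogs. Next came Adam11, from 3.25 ± 0.940 to 60.5 ± 34.9 (3.59 ± 0.441, 0.000101, chromosome 11, 102761439 to 102780262), and Cyp4a14, a fatty acid hydroxylase gene, from 78.6 ± 83.1 to 699 ± 215 (3.56 ± 0.495, 0.000211, chromosome 4, 115486200 to 115496142). The largest downward were in Idi1, at 102 ± 21.6 and 19.2 ± 25.6 TPM (−3.08 ± 0.560, 0.000982), and in Nnmt, at 138 ± 17.3 and 18.9 ± 10.4 (−2.96 ± 0.440, 0.000305). The lectin gene Clec2h was at 9.07 ± 2.67 and 0.35 ± 0.238 (−2.87 ± 0.278, 2.35e-05, chromosome 6, 128662385 to 128677374). Without FGF21 replicate 1 the fold change of Adam11 was 4.17 and that of Idi1 −3.84, and without chow replicate 2 that of Cyp4a14 was 4.17.

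Of 25 cholesterol biosynthesis genes 19 were lower than in chow (19 adjusted over the list alone, median −1.14, camera adjusted p = 9.29e-11, adjusted p = 0.263 with an estimated correlation). Tm7sf2 was at 281 ± 12.1 TPM in chow and 128 ± 22.1 with FGF21, and Msmo1 at 87.5 ± 13.9 and 15.6 ± 15.0. Mitochondrially encoded genes were lower in 10 of 13 cases, 11 adjusted over the list alone (camera adjusted p = 1.47e-07, adjusted p = 0.234 with an estimated correlation), with mt-Cytb at 12031 ± 3189 and 3713 ± 2080 TPM and mt-Nd4 at 7830 ± 947 and 4258 ± 1028. With the GC trend removed 6 of them were lower, and mt-Nd4 went from −0.90 ± 0.161 to −0.28 and was no longer called (adjusted p = 0.232). Genes of fatty acid oxidation and ketogenesis were higher in 24 of 30 cases, 25 adjusted over the list alone, with Ehhadh at 89.0 ± 9.54 and 286 ± 82.7 TPM and Vnn1 at 24.2 ± 10.7 and 92.7 ± 21.8 (camera adjusted p = 2.72e-05, adjusted p = 0.305 with an estimated correlation).

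Sinusoidal endothelial markers were higher in 13 of 16 cases, 13 adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.374 with an estimated correlation). The von Willebrand factor gene Vwf was at 3.25 ± 0.759 and 10.8 ± 1.96 TPM and the endoglin gene Eng at 61.1 ± 8.85 and 139 ± 27.5. The RNA is of whole liver, so both can come from endothelium outside the sinusoids. No change in sinusoidal cells follows from them. Kupffer cell markers were higher in 10 of 12 cases, 11 adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.282 with an estimated correlation). Lysosome genes were higher in 20 of 27 cases (21 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.282 with an estimated correlation). Recruited macrophage markers were higher in 10 of 16, 10 adjusted over the list alone (camera adjusted p = 0.00294, adjusted p = 0.282 with an estimated correlation). Matrix genes were higher in 13 of 24 cases, 13 adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.66 with an estimated correlation), and stellate cell markers in 11 of 15, 12 adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.395 with an estimated correlation). Interferon response genes were higher in 12 of 22, 13 adjusted over the list alone (camera adjusted p = 0.0274, adjusted p = 0.594 with an estimated correlation). With the GC trend removed, 4 matrix genes, 4 stellate cell markers and 5 interferon response genes were higher.

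Lower than in chow were also periportal markers, with 7 of 16 lower and Cdh1 and Ctsc higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.342 with an estimated correlation), and male-biased hepatocyte genes, with Mup20, Cyp4a12a, Cyp4a12b, Cyp7b1 and Nudt7 of 19 lower and Ces2e higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.489 with an estimated correlation). On the male-biased list chow replicate 2 (−0.82 from the chow mean) lay below FGF21 replicates 2, 3 and 4 (−0.32, −0.39 and −0.08), and FGF21 replicate 1 was at −0.93. Drug-metabolising enzymes also passed as lower than in chow, with 11 of 26 lower and 9 higher (12 and 9 adjusted over the list alone, camera adjusted p = 0.00921, adjusted p = 0.282 with an estimated correlation), as did oxidative phosphorylation, with 6 of 29 lower (4 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.257 with an estimated correlation). Bile acid genes, with 7 of 23 lower and 6 higher, passed as lower with a median of −0.05 (8 and 7 adjusted over the list alone, camera adjusted p = 0.0437, adjusted p = 0.34 with an estimated correlation). Drug-metabolising enzymes did not pass with the GC trend removed (0.112). Bile acid genes did not pass without FGF21 replicates 1 (0.0666) or 3 (0.0809), interferon genes without chow replicate 3 (0.0778) or FGF21 replicate 1 (0.184), and stellate cell markers without FGF21 replicate 1 (0.0529). Other lists passed only in some fits without a library: antigen presentation genes (0.0191 to 0.0441), neutrophil markers (0.0254 to 0.0468), female-biased genes without chow replicate 2 (0.0264) and NRF2 genes without FGF21 replicate 2 (0.0311). On the female-biased list chow replicate 2 was at 1.11 from the chow mean, against −0.42 to −0.32 in the other chow libraries. The genes of this paragraph were named after their values were seen.

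In this contrast limma called 4153 genes higher and 1560 lower, and 3356 and 658 genes had groups that did not overlap (36.5% of genes, where chance gives 2.86%). Of 38 lists 15 passed with camera, 8 higher and 7 lower, and 0 with an estimated correlation, where 6460 single genes had an unadjusted p under 0.05 and fry called 26 lists. Without FGF21 replicates 1 and 3, 7 lists passed. Lost were recruited macrophage markers (camera adjusted p = 0.0514), matrix genes (0.0731), stellate cell markers (0.11), periportal markers (0.114), male-biased genes (0.11), drug-metabolising enzymes (0.0543), bile acid genes (0.168) and interferon response genes (0.27). With quantile normalization drug-metabolising enzymes (0.0719) and bile acid genes (0.0773) were lost. Calls split 72.7% higher on TPM and 48.8% with median-of-ratios scaling (2551 higher, 2681 lower) or 49.0% with quantile normalization (2528 and 2628). Spearman's rho of the fold changes with GC content was 0.61 across 10810 genes, and with that trend removed limma called 1675 genes higher and 1781 lower, which kept 2326 of the 5713 calls. That removal also took the median log2 fold change from 0.20 to 0.01. Median-of-ratios scaling alone kept 4111 of the calls. Lower genes numbered 978 without chow replicate 2 and 950 without FGF21 replicate 2.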

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

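The tests of the acinar pancreas genes (3 tests), of GC slopes between libraries (2 tests) and of adipose tissue were chosen only after the result was seen. The rule for single libraries far from their group, the counts over other splits, the GC trend as the whole cause of the list calls and the GC test of the adipocyte genes were set before their results.

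In 14 of 198 groups of 4 values checked, a library lay far from the other 3, where chance alone gives about 9.9 groups, since about 1 in 20 is picked by chance. Chow replicate 2 was high for Ehhadh (103.3 TPM, others 83.4 to 85.5), Fgf21 (7.2, others 2.8 to 3.5), Klb (11.7, others 8.9 to 9), Cyp2a4 (3.1, others 0.1 to 0.2) and Cyp4a14 (202.6, others 27.1 to 47.5). Its Mmp12 was at 0.2 with 0.1 in the others, a single step of the rounding. MASH vehicle replicate 2 was high for Fgf21 (38.5, others 13.8 to 17.6), and replicate 3 was low for Msmo1 (9.6, others 15.5 to 16.3). FGF21 replicate 1 was high for Idi1 (57.4, others 3.1 to 8.8), mt-Cytb (6807.6, others 2313.1 to 2909.8) and Cyp2a4 (61.5, others 9.4 to 16.8). FGF21 replicate 3 was high for Mmp12 (0.8, others 0.2), and replicate 4 was low for Ly6d (4.9, others 15.3 to 17) and Fgf21 (5, others 11.5 to 12.6).

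Other splits of the same libraries were counted for each contrast. For MASH vehicle against chow the real split gave 4103 calls, the only 1 of 35 splits to give as many. The highest of the others gave 0 calls. A chance assignment of libraries was argued against, at a share of 0.0286, the smallest that 35 splits can give. For FGF21 against MASH vehicle the real split gave 1132 calls, again the only 1 of 35, with 0 as the highest of the others. Chance was argued against there at the same share. For FGF21 against chow the real split gave 5713 calls, 1 of 35, and the highest other split gave 2666, with FGF21 replicate 1 placed beside chow replicates 1, 2 and 3. Chance was argued against in this contrast too, at the same share. The highest other split moved a single library out of each group, so it kept part of the group difference. Structure among the libraries beyond the groups was not tested. Splits that mix the groups hold the group difference in their spread, which lowers their calls. No split can tell whether the libraries are separate animals, and the shares were not adjusted.

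Of 38 acinar pancreas genes listed, 8 were in the table, and all 8 were highest in FGF21 replicates 1 and 3. A response of the liver to FGF21 was argued against, because in FGF21 replicates 2 and 4 the median log2 difference of these genes from MASH vehicle was −0.0515, against 4.95 in replicates 1 and 3. Pancreas tissue in the sample stays open for the genes other than Reg2, whose excess in replicate 1 over that in replicate 3 kept nearly 1 ratio in 5 genes (0.690 to 0.866, highest over lowest 1.25). Pancreas tissue of the same makeup in both samples was argued against for Reg2, whose ratio of 5.16 was 7.14 times the median of the others. Over all 6 genes the spread of the ratios was 7.47, and Reg2 was set apart only after that was seen. The totals of FGF21 replicates 1 and 3 fell short of 1000000 TPM by 7968 and 8206. Whether acinar genes absent from the table account for this was not tested, so the genes shown may not give the full size of the pancreatic share.

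Fold changes rose with GC content in all 3 contrasts. For MASH vehicle against chow the median log2 fold change per bin of GC content peaked at 0.361, at 53.0% GC. It was 0.253 in the highest bin. The GC trend as the whole cause of the list calls was argued against, since 21 of 22 lists for the diet and 18 of 19 for FGF21 stayed past the threshold in their direction after its removal. A GC bias that differs from library to library stays open for FGF21 against MASH vehicle, where slopes differed by 0.200 log2 units per 10 points of GC between groups and by up to 0.427 within a group (exact permutation p = 0.143), a range that rests on FGF21 replicate 1 alone (−0.0509, against 0.272 to 0.376 in the other FGF21 libraries and at most 0.124 in MASH vehicle). For MASH vehicle against chow a library bias and an effect of the diet cannot be told apart, because slopes differed by 0.301 between the groups and by up to 0.240 within a group (exact permutation p = 0.0286). For FGF21 against chow the slopes differed most, by 0.501 between the groups, and a library bias was not weighed there. An effect of diet or of FGF21 on GC-rich genes stays open as untested.

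Cfd, Cidea, Cidec and Plin4, genes typical of adipocytes, rose on the MASH diet. Adipose tissue in the sample was argued against, because Adipoq averaged 0.125 TPM in MASH vehicle, 0.882% of the 14.2 TPM that Cfd there would need at the higher ratio of Cfd to Adipoq of FGF21 replicates 1 and 3. These were the only libraries with Adipoq above 0.2 TPM, and the ratio of 17.5 rests on replicate 3 alone. The GC trend of the libraries was argued against too, since the smallest of the 4 log2 fold changes was 3.43 after its removal. As a hypothesis, found and tested on the same data, expression of these genes by liver cells on the MASH diet stays open as untested.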

How the results depend on the processing

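The alternatives chosen only after the data were seen were removal of the GC trend, removal of the GC and length trends, leaving out FGF21 replicates 1 and 3, and leaving Mup and mitochondrial genes out of the total. Where no reason is given, the cause was not tested. TPM keeps no depth, so what depth limits cannot be given.

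For MASH vehicle against chow, genes higher and lower numbered 1592 and 1980 with median-of-ratios scaling, 1683 and 1986 with quantile normalization, 1507 and 1383 with the GC trend removed, and 1557 and 1527 with GC and length removed. Array weights gave 1355 lower, and an absolute log2 fold change of at least 1 left 510 and 140. For FGF21 against MASH vehicle they were 348 and 283 with only the 2 groups fitted, 1415 and 1054 with array weights, 1767 and 1221 without FGF21 replicates 1 and 3, and 58 and 99 with an absolute log2 fold change of at least 1. For FGF21 against chow, median-of-ratios scaling gave 2551 and 2681, quantile normalization 2528 and 2628, and the fold limit 566 and 174. Genes higher were 1675 and 1610 with GC, or GC and length, removed, and genes lower were 1030 at a TPM of at least 5, where fewer genes were tested.

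Genes opposite in the diet and FGF21 contrasts numbered 707 with array weights and 124 with split MASH vehicle libraries, where each contrast had fewer libraries. Genes in the same direction numbered 38 with median-of-ratios scaling, 40 with quantile normalization, 511 with array weights, 192 with the replicate block, 22 with GC removed, 20 with GC and length removed, 890 without FGF21 replicates 1 and 3, 47 without Mup and mitochondrial genes, and 12.8 with split libraries.

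Leaving out 1 library gave 2317 to 3739 genes higher and 487 to 1195 lower for the diet, 285 to 1274 and 228 to 943 for FGF21 against MASH vehicle, and 3362 to 4446 and 950 to 2028 for FGF21 against chow. It gave 209 to 557 opposite genes, 15 to 410 in the same direction, and 20 to 25, 17 to 21 and 12 to 18 lists.

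With an estimated correlation camera called 0, 0 and 0 lists, at a smallest adjusted p of 0.167, 0.167 and 0.234. That setting allows for the correlation of members. Whether this correlation alone led to the loss of the lists was not tested. For FGF21 against chow 7 lists passed without FGF21 replicates 1 and 3, and 26 with fry. Acta2 turned to −0.75 for FGF21 against MASH vehicle without FGF21 replicates 1 and 3. With quantile normalization hepatocyte secreted proteins turned (adjusted p = 0.781 for the diet, 0.0262 for FGF21 against chow). Fry tests a list against no change and camera against the other genes, whose median was above 0. Fry thus called as higher 4 lists that camera had as lower without passing: oxidative phosphorylation (0.0193) and FGF receptor signalling (0.00706) for the diet, and gluconeogenesis and glycolysis (0.0424) and the insulin and growth hormone axis (0.0297) for FGF21 against chow.

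Of 78 results of named genes, 75 kept their direction and side of the threshold with the GC trend removed, 77 with median-of-ratios scaling, and 78 without the trend and robust options. Of 114 results of lists these were 105, 107 and 114, against 58 with an estimated correlation, 80 with fry, 97 with GC and length removed, 91 of 111 without FGF21 replicates 1 and 3, and 96 of 105 at a TPM of at least 5.

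With the replicate block limma called 3630 genes higher and 1058 lower for the diet, 958 and 635 for FGF21 against MASH vehicle, and 4389 and 1722 for FGF21 against chow. Libraries of the same number correlated at −0.18 to 0.41 after group means were removed, 7 of 12 pairs above 0.1, and 7 of 12 libraries correlated best with their own number. These correlations alone lean toward pairing. With group means removed, GC slopes were negative for replicate 1 in chow, MASH vehicle and FGF21 (−0.0569, −0.0810 and −0.284). For replicate 4 they were positive (0.116, 0.0904 and 0.143), and for replicates 2 and 3 the sign differed between groups. Whether the GC trend gives rise to the correlations was not tested. At no replicate number do the library names of all groups carry the same number, so the names do not back a pairing. Not every pair was above 0.1 and the labels give the replicate numbers no meaning, so the block was kept out of the main model. With it Fgf21 (adjusted p = 0.0163), Adgre1 (0.0396) and Cd74 (0.0285) passed as lower for FGF21 against MASH vehicle, and the cAMP targets did not pass for the diet or for FGF21 (0.054 each).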

Other observations

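The single genes of this part, and so their tests, were chosen only after the result was seen, while its 2 lists were fixed before. The fixed list of FGF receptor signalling did not pass for the diet (4 of 19 higher and 1 lower, camera adjusted p = 0.896) or for FGF21 against MASH vehicle (2 and 2, 0.891). Fgfr4, the main FGF receptor of hepatocytes, fell on the MASH diet from 48.5 ± 4.94 to 32.2 ± 2.47 TPM (mean ± SD, n = 4, limma adjusted p = 0.00226) and rose with FGF21 to 54.9 ± 6.99 (adjusted p = 0.00259). Atf3 and Jun rose on the diet, from 0.45 ± 0.0577 to 3.68 ± 1.28 TPM (adjusted p = 1.61e-05) and from 5.22 ± 0.386 to 14.2 ± 4.68 (0.000243). With FGF21 they fell to 0.87 ± 0.171 (0.00106) and 5.78 ± 0.660 (0.00344).

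The fixed list of gluconeogenesis and glycolysis did not pass for the diet (5 of 20 higher and 5 lower, camera adjusted p = 0.134) or for FGF21 against MASH vehicle (1 and 1, 0.0788), where it passed as higher without MASH vehicle replicate 3 (0.0332) and without FGF21 replicates 1 and 3 (0.0355). Its member G6pc, which encodes glucose-6-phosphatase, fell on the diet from 153 ± 10.1 to 64.3 ± 10.2 TPM (limma adjusted p = 2.13e-05) and rose with FGF21 to 143 ± 20.4 (0.000379). Apoa4, an apolipoprotein gene, rose from 931 to 11595 TPM (3.05e-06) and fell to 4673 (0.0143). The methionine cycle gene Gnmt fell on the diet from 3884 ± 216 to 1172 ± 184 TPM (3.4e-06) and was at 1468 ± 270 with FGF21, which did not pass (0.172).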
